A study of Mus musculus with 2 samples.

How the data were processed

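RNA of 2 samples was hybridised to 1 array each: mouse bone marrow cells exposed to ID8 tumour cells (ID8-induced MDSC) and control bone marrow cells. Per the labels' protocols, marrow cells were grown in medium with 5% FBS, RNA was extracted with TRIzol, and biotinylated cRNA was made from 6 ug of total RNA by the Affymetrix procedure. Per the submitters' processing notes, MAS5 was used. Its version, its scaling target and its detection calls are not given in the sources used here. The deposited values are MAS5 signal intensity on a linear scale, 1 per probe set, for 45037 probe sets and no control probe sets. The trimmed means of the 2 columns differed by little (219.6 and 222.2), so they had the same scale. The scanner files were not used here.

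Before any comparison, each column was checked for whether its values follow their probe sets. Rises from row to row were counted, over the whole column and separately for values at or above and below the column's last value. In the control column the values stood in 2 interleaved descending sequences. No label or header gives a reason for that order, and no other order of the values could be recovered. The comparison fixed before the data were examined, a count of genes at least 2-fold higher or lower with 1 array per group and no test, was therefore not reported as a result. Only its count beside that from control values dealt out at random is given in the closing section. The checks were tested on simulated data for 18193 genes. The simulated control was the ID8-induced column itself with random noise and 200 genes lowered 4-fold. With its values in place it gave 22471 rises and 209 genes past 2-fold. The same values put in the rank order of the deposited control gave 0 rises and 9784 genes.

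The ID8-induced column was then described alone, as deposited, without further scaling. Probe sets were named from GEO's platform annotation: 34945 carried 1 gene symbol, 932 several and 9160 none, and only the first kind was used. Of these, 34741 had an Entrez ID found in the table of the GRCm38.p6 assembly, and 0 symbols needed updating. A gene was represented by its brightest probe set, which raises the level of genes with many probe sets. Among the 9010 genes with several, the median ratio of the brightest to the dimmest was 3.01, and for 3936 the dimmest lay below the floor while the brightest did not. With no replicates, this disagreement is the only check available within the array. It also reflects how well each probe set hybridises, so it is not the error of a signal. It does not cover the spread between cultures. The floor was the 40th percentile of this array (68.77), a change made after the data were seen from the written design, which took it from both scaled columns, and 12973 of 18193 genes (71.3%) passed it. A gene's percentile is the share of all probe sets with a lower signal, and it places the signal on the scale of the array without ranking transcripts by abundance.

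The 37 gene lists, with 837 distinct symbols, were fixed before the data were examined, and 755 of the symbols had a probe set named for them alone. A list was summarised by its members above the floor, its median percentile with a 95% bootstrap interval over members (2000 draws), and the share of 10000 random lists of the same size with a lower median. Random lists were drawn from all named genes and not matched on signal, since matching on the quantity described would fix the outcome. Well-studied genes tend to be bright, so a high share is not specific to a list. In simulations 10 of 200 random lists exceeded 95% of draws, and so did 42 of 50 lists raised by 25 percentile points. The rule for named genes was written for fold changes and could not be applied. In its place, chosen after the data were seen, came the 8 measured genes of the 9 always to be named and the 12 genes with the strongest signals. Added to these were the strongest members of each list, up to 4, and in some lists a few members below the floor. Alternatives were floors at the 20th and 60th percentile, the mean log2 signal over all probe sets of a gene, probe sets without a suffix letter only and the floor from both columns as first written, which was run as an alternative once the main floor had changed. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.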

Results

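Gene expression was profiled on Affymetrix arrays in mouse bone marrow cells that had been exposed to ID8 tumour cells and in control bone marrow cells, both from C57BL/6 femurs. ID8 is a mouse ovarian surface epithelial tumour line (the labels write it both as ID8 and as 1D8). The sample's title names tumour cell supernatant as the inducer, while the treatment protocol describes tumour cells in the upper chamber of a 24-well transwell plate, above the marrow cells, for 4 days. The protocol describes the product as CD11b+Gr1+ myeloid-derived suppressor cells (MDSC), immature myeloid cells that restrain T cells. The control was labelled only as bone marrow cells. The labels gave it the same CD11b+Gr1+ phenotype, and they did not state whether it was kept in culture as long. Each group held 1 array, so no value below has a replicate error and no difference between groups could be tested. The number of arrays limits the precision throughout.

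The design asked which genes differed between ID8-induced MDSC and control marrow cells. That comparison could not be made gene by gene from the value table used here, because the control signals fell in order along the probe set IDs. Down the 45037 rows, which are ordered by probe set ID, the control signals formed 2 non-rising sequences. Of these, 22626 values at or above 91.67 and 22411 values below it each contained 0 rises from row to row. Split in the same way at its own last value, the ID8-induced column had 10622 and 11804 rises. Over the whole columns, 3103 of 45036 steps (6.9%) were rises in the control, where the sequences alternate, and 22454 (49.9%) in the ID8-induced array. The first row of the table, a probe set of Copg1 (a coat protein of transport vesicles), carried the highest control signal of the array, 26083.92, against 358.17 in the ID8-induced column.

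**Figure D1:**
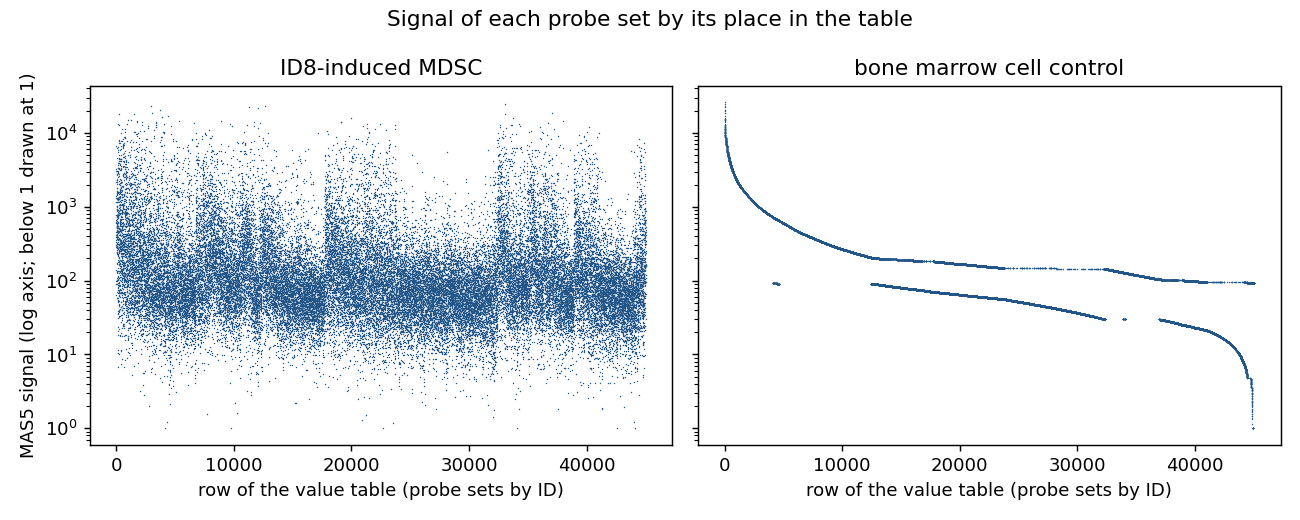
Each point is 1 probe set: the x axis is its row in the value table, ordered by probe set ID, and the y axis its MAS5 signal on a log axis, for ID8-induced MDSC (left, 1 array) and the bone marrow cell control (right, 1 array). The ID8-induced signals scatter at every row, and the control signals lie on 2 falling curves, one at or above 91.67 and one below it.

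The distribution of control signals does not depend on their order and was close to that of the ID8-induced array. The 2% trimmed mean was 219.6 for ID8-induced MDSC and 222.2 for the control, the median was 89.52 and 92.31, and the 99th percentile was 4651 and 4025. The 100 strongest probe sets held 8.83% of the summed signal in ID8-induced MDSC and 8.23% in the control. With 1 array each, these differences have no error against which to set them. All values that follow are from the ID8-induced array alone. They describe that sample and do not show that any gene was raised or lowered by the tumour cells.

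Neutrophil and suppressor-cell transcripts gave strong signals in ID8-induced MDSC. Arg1 (arginase 1, which consumes arginine) read 6587, Nos2 (inducible nitric oxide synthase) 2364, Cybb (the catalytic subunit of the phagocyte NADPH oxidase) 4706 and Ptgs2 (cyclooxygenase 2) 4732. The transcription factor gene Cebpb read 10975. Among 23 measured suppressive effectors, 22 lay above the signal floor of 68.77 and 13 at or above the 99th percentile of the array. The floor is the array's 40th percentile (no detection calls were given), and 71.3% of all 18193 genes passed it. A count near that share does not set a list apart. S100a9 and S100a8, the subunits of calprotectin, read 24857 and 20545, Ncf1 (another oxidase subunit) 10020, and Ido1 lay below the floor at 59.33. The median percentile of this list was 99 (95% bootstrap interval over members 96.2 to 99.5). It lay above all of 10000 random gene lists of its size, as did the medians of 16 of the 37 lists, ribosomal protein and housekeeping genes included, and 10 of its members belong to other lists too. Ddit3 read 1910 and Stat3 1738 on their brightest probe sets, and 624.64 and 233.81 on their dimmest. Itgam, which encodes CD11b, read 2375. Ly6g, which encodes one of the antigens bound by Gr1 antibody, is not analysed here because no probe set was named for it alone.

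Transcripts of late neutrophil granules and of neutrophil maturation were above the floor for 22 of 22 measured genes. Each was at or above the 90th percentile. Lcn2 (lipocalin 2) read 21448, Ngp (neutrophilic granule protein) 18326, and the list's median percentile was 99.2 (98.3 to 99.8). All 14 measured genes of the list for primary granules and promyelocytes, the earlier stage, also passed the floor, and 3 of the 14 reached the 90th percentile. Membership of the list does not by itself make a gene particular to that stage. The strongest members of that list were Igsf6 at 3437, Rab44 at 2925, Prtn3 (proteinase 3) at 1229 and Fcnb (ficolin B) at 466. Its members Ctsg, Elane, Mpo and Ms4a3 read 413, 301, 278 and 157. The median percentile of the list was 80.6 (68.2 to 87.1). Signals of different probe sets depend on how well each hybridises, so the lists are described side by side and not ranked.

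Monocyte and macrophage markers gave a mixed picture, with 20 of 27 above the floor. Their median percentile was 80.4 (56.3 to 95.6), and 99.29% of random lists had a lower median. Of these markers, 14 belong to other lists too. Lyz2 (lysozyme) read 10887, Cd14 10143, Mpeg1 5515 and Csf1r (the receptor of macrophage colony-stimulating factor) 4403. Markers of mature tissue macrophages lay on both sides of the floor. Adgre1 (F4/80) read 1443, C1qb 365, Vcam1 309, Gpnmb 295, Msr1 283 and Marco 173, while C1qa read 35.04, Mrc1 35.06, Mertk 48.62 and Cd163 17.09. The dimmest probe sets of C1qb, Gpnmb and Msr1 lay below the floor at 18.71, 32.69 and 44.09. Of 23 alternative activation genes, 17 passed the floor, among them Arg1, Chil3 at 5512, Tgm2 at 5036 (22.94 on its dimmest probe set) and Il10 at 859, while Mrc1 and Cd163 did not. For the alternative activation list the median percentile was 59.3 (50.2 to 90.5), within the range of random lists, of which 40.73% had a lower median. Dendritic cell and MHC class II genes passed the floor in 21 of 22 cases, with H2-Ab1 at 1531, Cd74 (the invariant chain) at 999, Irf8 at 431 and H2-Aa at 372, but 2 of the 22 reached the 90th percentile and random lists had a lower median in 72.69% of draws.

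Inflammatory mediators were represented by 29 of 33 genes above the floor, 11 of them at or above the 99th percentile. Nfkbia (an inhibitor and target of NF-kB) read 16872, the chemokine genes Ccl3 and Cxcl2 16508 and 13279, and Il1rn (the interleukin 1 receptor antagonist) 8377. The 4 genes below the floor included Cxcl5 at 45.61 and Ccl12 at 25.57. All 30 measured interferon-stimulated genes passed the floor, led by Rsad2 (viperin) at 6342, Trim30a at 2917, Rtp4 at 2902 (145.64 on its dimmest probe set) and Oasl2 at 2258. Pattern recognition and Fc receptors passed in 27 of 29 cases, with Fcer1g at 11534, Tyrobp at 10322 and Clec4e at 9740. Cytokine and chemokine receptors passed in 32 of 33 cases, with Il1r2 (the interleukin 1 decoy receptor) at 8703, Tnfrsf1b at 5345, Ccr1 at 5013 and Ifnar2 at 4912 (390.14 on its dimmest).

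Immune checkpoint ligands and receptors were above the floor for 20 of 21 genes. Cd274, which encodes PD-L1, read 6888, Lgals3 (galectin 3) 12722 and Cd47 6207. The 5 probe sets of Cd47 disagreed, the dimmest reading 69.55. Havcr2, which encodes TIM-3, lay below the floor at 26.14. Among angiogenesis and matrix remodelling genes, 16 of 23 passed the floor, close to the share among all genes (71.3%). Mmp8 (neutrophil collagenase) read 9648, Thbs1 (thrombospondin 1) 5096, Prok2 (prokineticin 2) 3695 with 42.26 on its dimmest probe set, and Mmp9 (gelatinase B) 3517.

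Glycolysis and hypoxia genes passed the floor in 28 of 28 cases, and 14 lay at or above the 99th percentile. The glycolytic enzyme genes Aldoa, Pgk1 and Ldha read 15069, 14189 and 13313, and the glucose transporter gene Slc2a3 read 13257. Genes used by most cells were bright as well: Fth1 (ferritin heavy chain) read 22443, Tmsb4x (thymosin beta) 17784, Fau 14541, Eef1a1 14319 and Tpt1 15077, the last with 31.72 on its other probe set. The median percentile of the glycolysis and hypoxia list was 98.9 (98.4 to 99.7). Mitosis genes passed in 31 of 31 cases, with Top2a at 1488, Mki67 at 1123, Ube2c at 1040 and Ccna2 at 901, and S phase genes in 26 of 29, with Pcna at 1756 and Ccne2 at 1412. Their median percentiles were 86.6 (80.3 to 90.6) and 77.1 (66.2 to 82.9). With the mean over each gene's probe sets the mitosis median was 72.3 and the Top2a signal 204.

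Markers of other cells that bone marrow or the upper chamber could contribute lay mostly below the 90th percentile, where most probe sets lie by definition. Random lists had a lower median in 56.58% of draws for B lineage, 35.31% for erythroid and 24.64% for T and NK cell markers. The share was 12.75% for fibroblast and stromal and 6.83% for epithelial and mesothelial markers. For eosinophil, endothelial, and mast cell and basophil markers it was 3.58%, 1.96% and 0.19%. T and NK cell markers had 18 of 22 genes above the floor and 0 at the 90th percentile, with Zap70 at 417, Prf1 at 314 and Cd4 at 277. B lineage markers had 17 of 20 above it, with Ighm (the immunoglobulin mu chain) at 3593 on the brightest of 11 probe sets and 36.6 on the dimmest, and Pou2af1 at 812. Erythroid markers had 13 of 20 above it, with Alas2 (the erythroid haem synthesis enzyme) at 1693 and Tfrc at 1476. Hba-a1, Klf1 and Car1 lay below the floor at 51.32, 55.94 and 31.2. Epithelial and mesothelial markers, which ID8 cells could bring, had 14 of 19 above it (4 with the floor at the 60th percentile, 8 with the mean over probe sets) and 0 at the 90th percentile, with Cldn3 at 239, Upk1b at 170 and Epcam at 159. Wt1, Krt19 and Cdh1 lay below the floor at 52.31, 46.03 and 21.57. Fibroblast and stromal markers had 16 of 24 above the floor, with Acta2 at 790 and Col1a1 at 270.02. Endothelial markers had 7 of 15, mast cell and basophil markers 6 of 16 and eosinophil markers 3 of 7, with Egfl7 at 2096, Hdc (histidine decarboxylase) at 3658 and Prg2 at 445 as the brightest of each. Other genes named above whose dimmest probe set lay below the floor were H2-Aa (10.67), Top2a (54.87), Prf1 (62.51), Cd4 (66.01), Upk1b (3.76), Epcam (58.32), Acta2 (46.17) and Col1a1 (34.71). A signal above the floor is not by itself evidence that a gene was expressed.

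**Figure D2:**
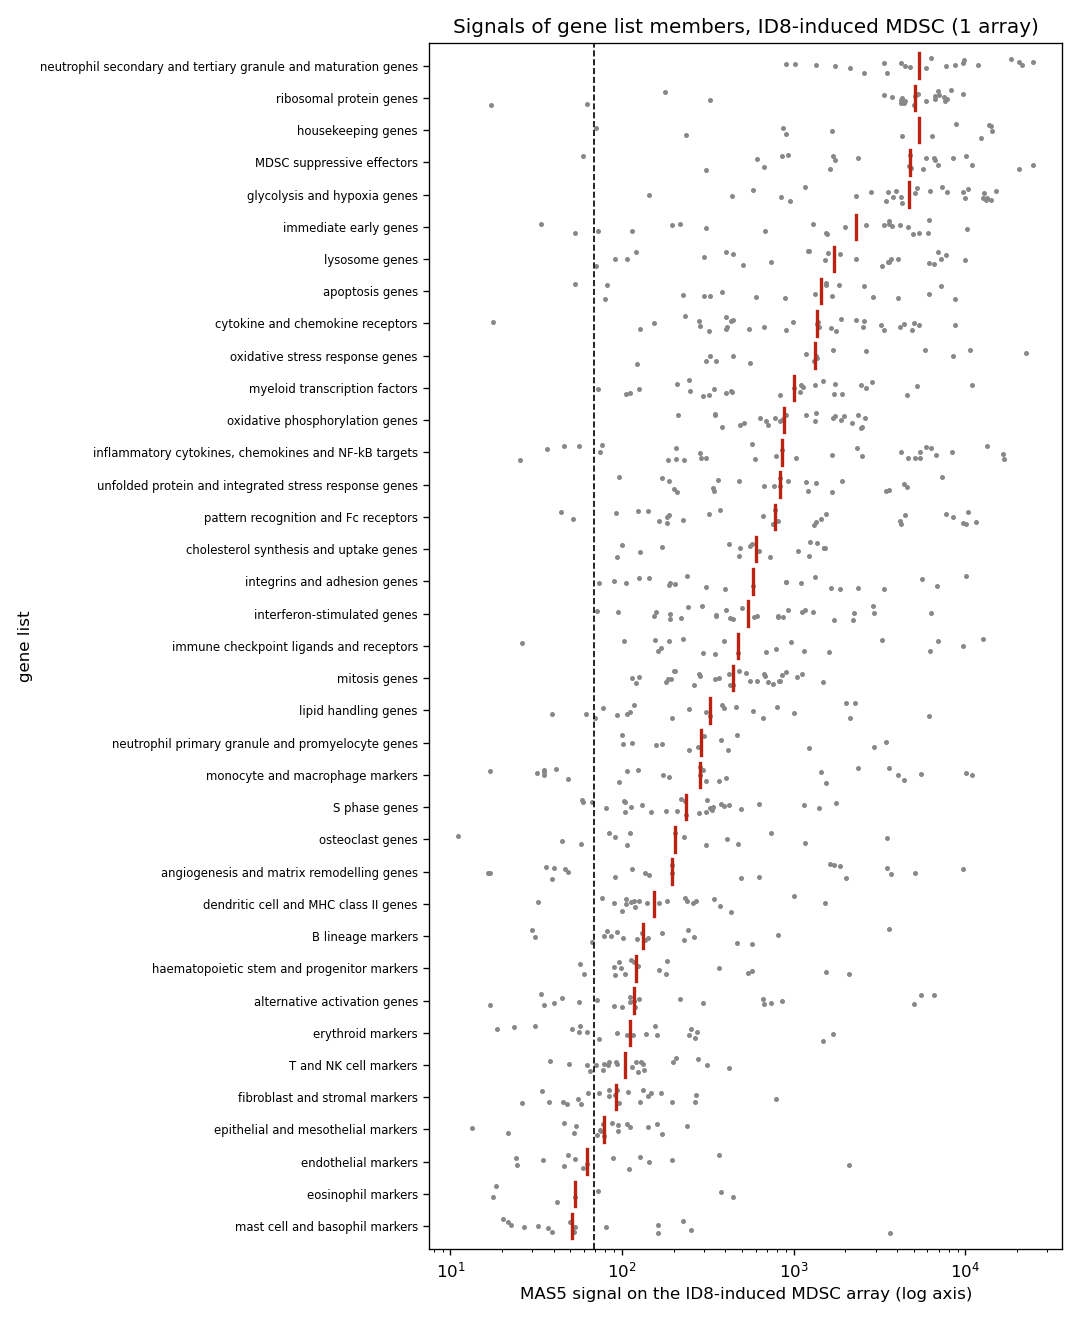
Each grey point is a gene's MAS5 signal (x axis, log scale) on the single ID8-induced MDSC array, grouped by gene list (y axis). Red bars are list medians and the dashed line is the floor of 68.77. The medians of the mast cell and basophil, eosinophil and endothelial lists lie below it. That of the late neutrophil granule and maturation list is 5354.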

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

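The 2-fold count given below was fixed before the data were examined. Its comparison with random deals, and every test in this part, was chosen after the order of the control column had been seen. The bone marrow cell control column held signals up to 26083.92, in the first row of the table, and a median close to that of the ID8-induced array. It was picked out because it is a measured column that no gene-level description uses. The pattern is that its signals fall down the probe set list. Within its 2 value ranges, 0 rises were counted, against 22471 in a simulated control with its values in place. A weak or degraded control array is argued against as the cause of the order, since noise has no order along the IDs while 6.9% of steps in the whole column were rises, against 49.9% in the ID8-induced column; this value follows from the order that prompted the test. The quality of the control array itself stays open, because the common scaling hides a weak signal. Another cell population in the control, the biological difference the design names, is argued against as the cause of the order by the same 6.9%, since the expression of other cells has no order along the IDs either. A real difference between the cell populations stays open and untested, since the order hides it. Signals sorted apart from their probe set IDs stay open as the cause, since no value used here tests it: the 0 rises restate the order, and correlations within blocks of rows, 2-fold counts and the control percentiles of gene lists, which were also tried, follow from it. How the order arose is not recorded in the sources used here.

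If the 2 columns were nevertheless compared as they stand, 3897 genes would be called at least 2-fold higher and 5927 at least 2-fold lower in ID8-induced MDSC, 9824 of 18193 in all. Dealing the control values out to all probe sets at random, 100 times, gave 10384 to 10643. A simulated control with its values in place gave 209. Dealt out at random its values gave 10296 to 10500, and in the rank order of the deposited column 9784. It was made from the ID8-induced column itself, with random noise and 200 genes lowered 4-fold. The 209 therefore does not show what a comparison of 2 cell populations would give. The counts of 9824, 3897 and 5927 each lie below every random deal (lowest 10384, 4348 and 5958). The control values were already known to stand in order, so nothing is concluded from this. The simulated sorted control comes close to 9824 largely by construction, and the count is not taken as a test. Fold changes taken from this table, Arg1 and the other named genes included, cannot be read as expression changes. Agreement between probe sets of a gene does not tell the columns apart. Across 9010 genes, the first and second probe set by ID had a Spearman rho of 0.507 in ID8-induced MDSC and 0.529 in the control. In the control, probe sets with close IDs can have close values by the order alone. The 0.529 therefore does not show that control values follow their genes. Between the 2 columns rho was 0.273 over all 45037 probe sets, with a median of -0.002 within blocks of 200 rows. Both depend on the order of the control and are not taken as a test.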

How the results depend on the processing

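The number of genes above the floor was 12973, and it moved by less than 1.5 times under each alternative run, from 9393 with the floor at the 60th percentile to 15924 with it at the 20th. It was 11376 with the mean log2 signal over a gene's probe sets, 11285 with probe sets without a suffix letter and 12977 with the floor from both columns. List medians left their bootstrap interval for 8 of 37 lists with the mean over probe sets: the mitosis median was then 72.3, T and NK cell 42.9, epithelial and mesothelial 35.2, integrin and adhesion 69.4, cholesterol 83.3, oxidative phosphorylation 89.4, ribosomal protein 97.8 and glycolysis and hypoxia 98. They left it for 2 with suffix-free probe sets: ribosomal protein fell to 64.2 and fibroblast and stromal to 36.1. Counts above the floor moved by over 1.5 times for 6 lists at the 60th percentile, so these depended on the floor. They were epithelial and mesothelial (4 of 19), T and NK cell (10 of 22) and dendritic cell and MHC class II (13 of 22). The others were alternative activation (10 of 23), fibroblast and stromal (9 of 24) and stem and progenitor (9 of 18). They moved for 3 lists at the 20th percentile, 1 with the mean and 6 with suffix-free probe sets. Of 149 named gene signals, 58 moved by over 1.5 times with the mean over probe sets, Stat3 to 824, Ddit3 to 1092, Rtp4 to 651, Ifnar2 to 1050, Nfkbia to 10196, Slc2a3 to 6289, Clec4e to 5440, Tnfrsf1b to 3534, Thbs1 to 3213, Ccr1 to 2398, Csf1r to 2054, Tgm2 to 1247, H2-Ab1 to 723, Tfrc to 443, Irf8 to 241, Zap70 to 173, Cldn3 to 149, Prf1 to 140, Cd4 to 135, H2-Aa to 116, Col1a1 to 97.38, Epcam to 96.4, Upk1b to 41.91 and, by over 5 times, Top2a to 204, Cd47 to 803, Ighm to 182, Tpt1 to 701, Egfl7 to 233, Prok2 to 316, Acta2 to 128, Ctsb to 1501, Npc2 to 1154, Mycn to 291, Slbp to 203, Sc5d to 238, Acadl to 282 and Rps24 to 1484. With suffix-free probe sets 15 of 113 moved, among them Cd47 to 2983, Ighm to 186, Top2a to 102, Xbp1 to 1132, Slc2a3 to 4222, Hif1a to 1590, Rps24 to 82.86 and Rps9 to 189.5, and Acta2 to 56.89, Prok2 to 42.26 and Tpt1 to 31.72, which lie below the floor. The signals of Cybb, Ptgs2 and Cebpb moved by less with the mean. Their brightest probe sets have no suffix letter, so suffix-free probe sets could not change them. Arg1, Nos2 and Itgam have 1 probe set each, without a suffix letter, so neither setting could change their signals. The planned rescalings (values as deposited, common median, quantile, loess), the offset without a floor, the rule that all probe sets agree in direction and the other fold thresholds were not run, because they act on the comparison that could not be made. No replicate could be left out.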

Other observations

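Other gene groups of the ID8-induced array, from the lists fixed before the data were examined, included strong stress and early-response signals. Of 24 immediate early genes 22 passed the floor, with Ier3 at 10285, Jun at 6154, Dusp1 at 6077 and Klf2 at 5348. All 24 genes of the unfolded protein and integrated stress responses passed it, with Ddit4 at 7347, Xbp1 at 4583, Hspa5 (BiP, an endoplasmic reticulum chaperone) at 4392 and Atf3 at 3572. The oxidative stress list passed in 16 of 16 cases, with Sod2 at 10671 and Hmox1 (haem oxygenase 1) at 8429, and apoptosis genes in 19 of 20, with Mcl1 (a survival factor of neutrophils) at 8663 and Cdkn1a at 7175. Myeloid transcription factors passed in 29 of 29 cases, with Hif1a at 5202 and Bhlhe40 at 4575 after Cebpb.

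Lysosome genes passed the floor in 26 of 26 cases, with Ctsb at 9966 and Ctsz at 7687, oxidative phosphorylation genes in 26 of 26, with Cox4i1 at 2604, cholesterol synthesis and uptake genes in 18 of 18, with Hmgcs1 at 1506, and lipid handling genes in 21 of 23, with Npc2 at 6167 and Plin2 at 2132, while Cd36 read 39.08. Integrins and adhesion genes passed in 23 of 23, with Cd9 at 10047 and Itgb2 at 6880, osteoclast genes in 12 of 15, with Tcirg1 at 1162, and stem and progenitor markers in 16 of 18, with Mycn at 1544 on the brightest of 3 probe sets and 83.83 on the dimmest. Ribosomal protein genes passed in 22 of 24 and housekeeping genes in 12 of 12, with median percentiles of 99.1 each. With suffix-free probe sets the ribosomal count was 9 and its median percentile 64.2. Members without such a probe set, Rpl4 and Rpl6 among them, drop out there, so the 9 is not out of 24. With the mean over a gene's probe sets several of these signals were lower by over 1.5 times: Ctsb read 1501, Npc2 1154, Sod2 2646, Hif1a 1709, Hspa5 1739, Xbp1 2612, Jun 3671, Mcl1 5632, Hmgcs1 808 and Mycn 291.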
